A study of Mus musculus with 6 samples.

How the data were processed

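Ascending aortas of 6 mice were profiled, 3 wild-type for Ldlr and 3 homozygous for a mutated Ldlr, with 1 array per mouse. Per the labels' protocols, total RNA was purified with a mirVana kit, its integrity was checked on a Bioanalyzer, and miRNAs were labelled with Cy3. Per the file headers, the arrays were a 1-colour Agilent mouse miRNA design, read by Agilent Feature Extraction 10.7.1.1. All 6 arrays lay on 1 slide and were scanned in 1 session on 1 scanner. Samples were grouped by the genotype and mouse in the labels. Replicate numbers follow the order of the samples and only name a mouse.

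The deposited scanner files hold spot intensity values on a linear scale, which the software had background-subtracted and spatially detrended per the file headers, with no normalization between arrays. The software's flags for detection, outliers and saturation were taken from the same deposited files. The software's total intensity per miRNA, also deposited, sums the probes of a miRNA and scales by spot size, and on mutant replicate 1 a default spot size of 0.6 was used, against about 0.80 on the other arrays. The authors' deposited value table holds log2 values that had been normalized between arrays, by a method not given in the sources used here. Its median was 2.56 in each of the 6 columns, and its values rank with the brightest probe of a miRNA on each array (Spearman rho 0.964 to 0.971 across 325 miRNAs, which are not independent replicates). The values were not centred per miRNA: on wild-type replicate 1 they were 13.2 for miR-143-3p and 2.55 for miR-342-5p. Whether another centring was applied and how probes were summarised stays unknown. Larger values mean brighter signal.

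Spots flagged as non-uniform or as population outliers were left out. The remaining spots of a probe were averaged, each array was divided by its 75th percentile over the 469 of 4415 probes well above background on all arrays, values were floored at the lowest scaled value of a detected probe (log2 -5.01), and log2 was taken. A miRNA was represented by its brightest probe, out of 1 to 4, and was tested if the software detected it on at least 3 of 6 arrays, which left 392 of 1881. Control spots and viral features did not enter, and the array held 0 viral features. The array has no saturated spot. Where a miRNA was not well above background on any array of a genotype, the fold is a lower bound: the brighter genotype's mean against, per array of the other, the higher of the lowest signal well above background and the probe's own. Values at the floor have no order.

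Changes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 392 miRNAs and a threshold of 0.05. The 19 lists of miRNAs were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, over the 17 lists that had at least 3 tested members. The viral list was empty and the epithelial list had 1 tested member. Single values were compared by an exact permutation test. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

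The lists, the tests, most alternatives and the rule for the miRNAs named were fixed before the data were examined. The rule takes the 12 largest changes past the threshold in each direction, up to 4 members past the threshold of each list or else its 2 brightest tested members, 14 miRNAs chosen beforehand, and miRNAs detected on all 3 arrays of one genotype and none of the other. MiR-150-5p, the heart muscle miRNAs and miR-30e-5p were named as list members after their values were seen, and so were miR-511-3p and the groups in the closing section that say so. MiR-150-3p, miR-206-3p and miR-378a-3p were also named after their values were seen.

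The same code was tested on simulated data for the comparison of mutant with wild-type: in 20 simulations of 392 miRNAs with 60 changed, 58.2% of the miRNAs changed by 0.5 on the log2 scale were recovered, 90.8% of those changed by 1 and 97.5% of those changed by 2, and 4.83% of the calls were false. The planted list was called in 20 of 20 simulations and an unrelated list in 0. The simulated miRNAs varied independently of each other and had no floor. The 0 therefore does not show how often lists are called falsely when miRNAs are correlated. Other splits of the real arrays gave up to 6 lists. Those splits mixed the genotypes unequally on each side and kept part of the genotype difference, so they do not count false calls either.

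Alternatives were other scalings (75th percentile over all probes, quantile, none, labelling spike-ins), normexp background correction with an offset of 50, the software's total signal, the authors' deposited table, the mean over probes, stricter and no filters on detection, population outlier spots kept, the slide row as a block and within row 1, the slide column as a covariate, a trended robust variance, array weights, and each array left out in turn. Chromosomes and neighbouring genes come from a RefSeq table of the GRCm38.p6 assembly, used for names only; 1853 of the 1881 miRNAs matched a precursor gene in it. The positions listed in the scanner files are headed as mm9, but of 627 miRNAs with a single listed position 32 lay inside their precursor on the other assembly, so no coordinates are printed. For arrays, precision is limited by their number.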

Results

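MicroRNA levels were measured in the ascending aorta of 6 mice, 3 of them wild-type for Ldlr and 3 homozygous for a mutated Ldlr. Ldlr encodes the low-density lipoprotein receptor, which clears cholesterol-rich lipoproteins from blood, and mice without a working receptor are a common model of atherosclerosis. The series text presents the mutant mice as the atherosclerosis group and the wild-type mice as the control group, and its title names inflammation and apoptosis. Each mouse gave 1 single-colour array, so n = 3 mice per genotype throughout. The array does not measure Ldlr mRNA, and the genotype of each mouse therefore rests on the labels alone.

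Of the 1881 mouse miRNAs on the array, the scanner software detected 390 ± 16.1 (SD, n = 3) per wild-type array and 373 ± 20.7 (SD, n = 3) per mutant array (two-sided exact permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow). The software detected 325 miRNAs on all 6 arrays and 1432 on none. Between 13.1% and 15.8% of the miRNA spots of an array were well above background, and no spot was saturated. The 75th percentile of the signal, taken over the 469 probes detected on all arrays, was 504 ± 64.0 (SD, n = 3) intensity units in wild-type and 401 ± 46.9 (SD, n = 3) in mutant arrays (two-sided exact permutation p = 0.2). Levels below are log2 values relative to that percentile, and changes are mutant minus wild-type.

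The comparison of mutant with wild-type aortas asks which miRNAs differ between the genotypes. The labels give no diet, age or sex of the mice, and the presence of lesions could not be checked. A difference in these between the groups could not be told apart from the mutation. The largest rises were of miRNAs known from white blood cells and inflammation. MiR-342-3p rose by 2.92 on the log2 scale (SE 0.17, adjusted p = 0.00104), miR-142a-3p by 2.73 (SE 0.31, adjusted p = 0.00666), miR-146b-5p by 2.72 (SE 0.14, adjusted p = 0.000802) and miR-146a-5p by 2.55 (SE 0.15, adjusted p = 0.00104). MiR-155-5p was not well above background on any wild-type array and was at least 5.68-fold higher in mutant arrays (adjusted p = 0.000389). Its 3 wild-type values were all set to the floor, with an SD of 0, so this adjusted p does not measure their spread. MiR-155-5p had a change of 1.13 with normexp correction, and with the software's total signal per miRNA it did not pass (change 2.52, SE 1.28). MiR-21a-5p, which is often raised in injured vessels, rose 3.90-fold, and miR-34a-5p, a target of the tumour suppressor p53, rose 4.57-fold. The falls were smaller, and the muscle miRNAs miR-1a-3p, miR-133a-3p, miR-143-3p and miR-145a-5p were among them. The adjusted p-values are those of a two-sided limma fit with Benjamini-Hochberg adjustment.

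Of 392 miRNAs tested, 94 passed an adjusted p of 0.05, with 33 higher and 61 lower in mutant arrays. The fitted change reached 2-fold in 14 rises and 3 falls, and with lower bounds in place of fitted changes where a genotype was at background, in 14 rises and 2 falls. At an unadjusted p under 0.05, 18 miRNAs had a fitted change of at least 2-fold, 14 of them upward. All 94 had non-overlapping values in the 3 mice of each genotype, as had 174 of the 392 tested (44.4%, against 10% by chance). Of these 94, 24 had at least 1 array at the floor, 10 of them rises and 14 falls. For miR-155-5p, miR-34c-5p and miR-142a-5p all 3 wild-type values were at the floor, as were all 3 mutant values of miR-133a-5p. The errors of such calls leave out the spread of values set to the floor. The median change of all 392 miRNAs was -0.10. The split into rises and falls depended on the scaling: 35.1% of the calls were rises here, against 18.5% when the percentile was taken over all probes, 10.2% with no scaling, 22 of 147 calls with scaling on the labelling spike-ins, 54.2% with normexp background correction and 22.8% with the software's total signal per miRNA.

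**Figure D1:**
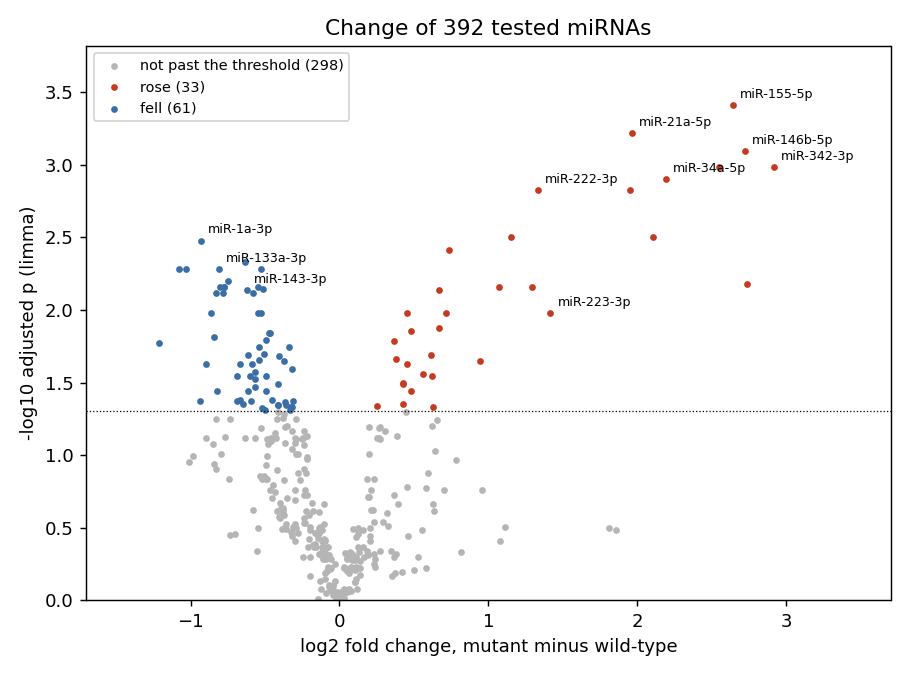
Change (log2, mutant minus wild-type) against -log10 of the limma adjusted p for each of the 392 tested miRNAs. Red points are the 33 miRNAs that rose, blue points the 61 that fell, grey points those that did not pass, and the dotted line marks an adjusted p of 0.05. The changes above 2 on the log2 scale are all rises.

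Of the 17 lists tested, 2 passed with the preset correlation of 0.01 between miRNAs, those of leukocytes and of the inflammatory response, and 0 with an estimated correlation. In the list of leukocyte miRNAs, 7 of 10 members were tested and all 7 rose; 5 of them passed with the slide row as a block, 4 within row 1 alone and 5 with the total signal. MiR-342-3p lies within Evl on chromosome 12, and its level was -2.32 ± 0.15 (SD, n = 3) in wild-type and 0.60 ± 0.29 (SD, n = 3) in mutant arrays. MiR-142a-3p is made in blood-forming cells. Its other arm, miR-142a-5p, was not well above background in wild-type arrays and was at least 2.23-fold higher in mutant arrays. The change of that arm was 1.29 in the main fit, 0.57 with normexp correction and 3.27 with the total signal. MiR-223-3p, a miRNA of myeloid cells, rose 2.67-fold (adjusted p = 0.0105), and miR-511-3p, whose precursor lies in the macrophage gene Mrc1, rose by 0.67 on the log2 scale. MiR-150-5p, an abundant miRNA of mature lymphocytes, was not detected on any array, but whether its probe responds could not be tested. The other arm, miR-150-3p, is not in the list and had a change of -0.55, against the direction of the list. The list's median change was 2.55, or 2.51 with lower bounds for the members at background. With the preset correlation, the camera test of limma gave an adjusted p of 5.4e-08, and with an estimated correlation an adjusted p of 0.122. All 7 also passed when adjusted over the list alone.

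In the list of the inflammatory response, 5 of 11 tested members rose and none fell; 7 rose when adjusted over the list alone, and 4 rose and 1 fell with the slide row as a block. The 5 were miR-146a-5p, miR-146b-5p, miR-155-5p, miR-21a-5p and miR-223-3p, of which 3 are also in the leukocyte list, so the lists are not independent. MiR-146a-5p and miR-146b-5p dampen signalling through NF-kappa B and share most of their sequence, so a probe for one can also bind the other. MiR-155-5p comes from Mir155hg on chromosome 16. MiR-21a-5p lies in Vmp1 on chromosome 11, and its level was 3.71 ± 0.12 (SD, n = 3) in wild-type and 5.67 ± 0.09 (SD, n = 3) in mutant arrays. Its other arm, miR-21a-3p, was detected by the software on all 3 mutant arrays and on no wild-type array, but no array had a probe of it well above background. The list's camera adjusted p was 5.4e-05 and the adjusted p with an estimated correlation was 0.243.

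In the list of apoptosis and p53, 4 of 13 tested members rose and 1 fell; 2 rose with the total signal, 2 with no detection filter and 1 within row 1. The rises were of miR-34a-5p, miR-34b-5p, miR-34c-5p and miR-15b-5p. MiR-34a-5p was at -0.68 ± 0.21 (SD, n = 3) in wild-type and 1.51 ± 0.16 (SD, n = 3) in mutant arrays. MiR-34b-5p and miR-34c-5p share a chromosome 9 locus and are similar in sequence. MiR-34b-5p had a probe well above background on 1 wild-type array and on 3 mutant arrays, and its change was 2.10 (SE 0.18, adjusted p = 0.00312), but -0.79 with the software's total signal per miRNA. MiR-34c-5p was at least 3.52-fold higher in mutant arrays, with a change of 0.77 with normexp correction, and did not pass with the total signal. MiR-15b-5p, within Smc4, rose 2.10-fold, whereas its neighbour miR-16-5p did not pass (change 0.07, SE 0.10). MiR-16-5p also has a precursor within Dleu2 on chromosome 14, so its level does not show the change of the Smc4 copy. The list as a whole did not pass (camera adjusted p = 0.39); its median change was -0.11 and its mean 0.41, which differ in sign. Without wild-type replicate 3 or any 1 of the mutant replicates, 0 members fell.

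**Figure D2:**
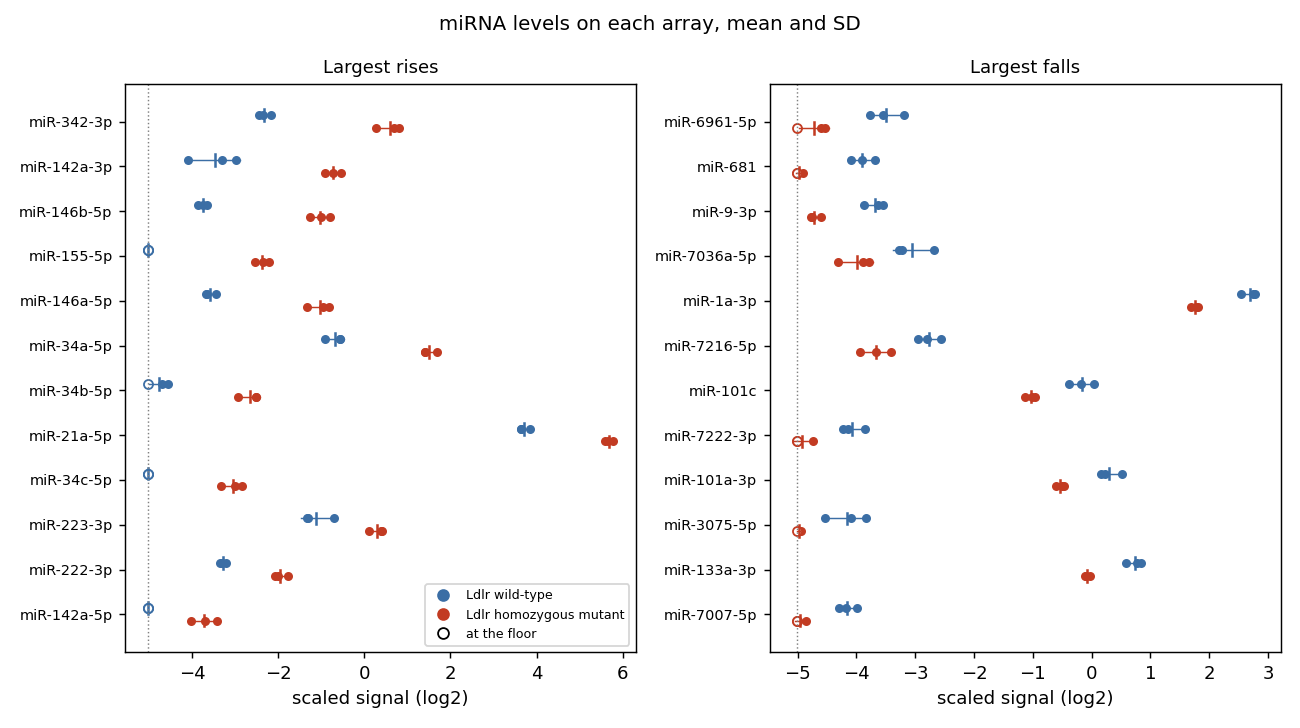
Scaled signal (log2) on each of the 3 wild-type (blue) and 3 mutant (red) arrays for the 12 miRNAs with the largest rises and the 12 with the largest falls past the threshold. Vertical ticks are means, horizontal lines span 1 SD on each side, open points lie at the floor of -5.01 (dotted line), and values of the genotypes do not overlap in any of them.

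MiRNAs of cardiac and skeletal muscle fell in 5 of 7 tested members. MiR-1a-3p, which promotes muscle differentiation, was at 2.69 ± 0.13 (SD, n = 3) in wild-type and 1.76 ± 0.06 (SD, n = 3) in mutant arrays and was 1.91-fold lower in mutant arrays (adjusted p = 0.00333). MiR-133a-3p was 1.76-fold lower and miR-133b-3p 1.71-fold lower, and these 2 sequences are nearly identical. MiR-133a-5p was at least 1.15-fold lower, since its mutant arrays were at background, and its change was 0.03 with normexp correction. The fifth was miR-30e-5p. MiR-206-3p and miR-378a-3p, at 0.05 and 0.24, did not pass. MiR-208a-3p, miR-208b-3p and miR-499-5p, which mark heart muscle, were not detected on any array. Whether their probes respond was not tested, so heart muscle in the samples is not excluded. The list's median was -0.63, or -0.57 with lower bounds. Its camera adjusted p was 0.0646, with an adjusted p of 0.998 for an estimated correlation. The fry test of limma, which asks whether a list moves one way on balance, gave an adjusted p of 0.0104. Fry does not compare a list with the other miRNAs, so the median change of -0.10 over all miRNAs counts towards a fall. With fry the leukocyte and inflammatory lists also passed (adjusted p = 2.1e-04 and 3.8e-04), and no other list did. At the preset correlation the list passed the camera threshold with wild-type replicate 1 or mutant replicate 1 left out, with quantile normalization, with normexp correction and with no detection filter. With no detection filter, however, 0 of its members fell past the threshold. With 1 array left out 4 members fell, or 5 without mutant replicate 1.

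Among the 12 tested smooth muscle miRNAs, 5 fell and 2 rose. The count of falls was 2 without wild-type replicate 2, wild-type replicate 3, mutant replicate 1 or mutant replicate 3, 3 without mutant replicate 2, 2 with the authors' value table, and 0 within row 1. MiR-143-3p and miR-145a-5p, which maintain the contractile state of smooth muscle and are made from Carmn on chromosome 18, fell 1.54-fold and 1.46-fold (adjusted p = 0.00726 and 0.0179). MiR-26a-5p fell by 0.37 on the log2 scale. MiR-222-3p and miR-221-3p, a pair on the X chromosome that promotes smooth muscle proliferation, rose 2.52-fold and 2.22-fold (adjusted p = 0.0015 and 0.00312). The list did not pass (camera adjusted p = 0.451), and its median was -0.33, or -0.28 with lower bounds.

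No list of another cell type passed the threshold with all 6 arrays and the main settings. In the endothelial list 1 of 6 tested members fell, miR-218-5p, while miR-126a-3p, the main endothelial miRNA, was 1.56-fold higher without passing (change 0.64, SE 0.22, adjusted p = 0.0932); it passed with normexp correction, with the authors' value table, with the trended robust fit and without wild-type replicate 2, at changes of 0.59, 0.77, 0.64 and 0.84. None of the 4 tested erythroid miRNAs passed, and miR-451a, the main miRNA of red blood cells, had a change of 0.46 (SE 0.33, adjusted p = 0.361). Without wild-type replicate 3 its change was 0.77, and the erythroid list, with a median of 0.64, then passed (camera adjusted p = 0.0455, against 0.18 to 0.877 under the other alternatives); without wild-type replicate 1 these changes were 0.27 and 0.15. In perivascular fat 1 of 7 fell, miR-365-3p. In neurons and glia 2 of 6 fell, miR-9-3p and miR-338-3p, and miR-7a-5p rose by 0.38, against -0.036 with the total signal. With normexp correction 0 members of that list passed, and miR-9-3p, miR-338-3p and the endothelial miR-218-5p had changes of -0.094, -0.26 and -0.038. None of 4 cartilage miRNAs passed, with changes of -0.09 (SE 0.10) for miR-140-3p and -0.16 (SE 0.11) for miR-140-5p. The single tested epithelial miRNA, miR-31-5p, had a change of 0.13 (SE 0.18). The list medians were -0.25 for endothelium, 0.29 for erythroid, 0.08 for fat, -0.04 for neurons and glia and -0.07 for cartilage. The falls in endothelium and in fat passed without wild-type replicate 1 but not without any other single array. In neurons and glia 2 fell without wild-type replicate 3 and 1 without any other single array, and among these fits the rise passed only without wild-type replicate 2.

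Of 12 tested miRNAs of cholesterol and lipid handling, 3 fell: miR-30c-5p, miR-224-5p and miR-26a-5p, by 0.55, 0.53 and 0.37 on the log2 scale. MiR-33-5p, encoded in the cholesterol regulator Srebf2, was detected too rarely to be tested. MiR-122-5p, the main miRNA of the liver, was above the floor on 1 wild-type and 2 mutant arrays and varied widely (-3.48 ± 2.65 in wild-type and -3.62 ± 1.25 in mutant arrays, SD, n = 3). In the list of miR-29 and fibrosis, miR-29c-3p and miR-29c-5p fell by 0.61 and 0.48 and miR-21a-5p rose, out of 10 tested. None of the 9 tested let-7 members and none of the 10 tested members of the miR-17 to miR-92 clusters passed; let-7c-5p had a change of -0.06 (SE 0.08) and miR-25-3p of 0.13 (SE 0.08). The camera adjusted p was 0.987 for the cholesterol list, 0.997 for the fibrosis list, 0.987 for let-7 and 0.517 for the miR-17 to miR-92 clusters. Without mutant replicate 1, 1 cholesterol miRNA fell. With normexp correction the change of miR-29c-5p was -0.19 and it did not pass. In the fibrosis list 0 fell without mutant replicate 1 or 3, 1 fell without mutant replicate 2, and 2 rose without wild-type replicate 2; without mutant replicate 3, 1 member of the miR-17 to miR-92 clusters rose.

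Among 17 tested miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, 3 fell: miR-434-3p by 0.32, miR-376c-3p by 0.32 and miR-377-3p, which was at background in mutant arrays. With normexp correction 0 fell, and miR-376c-3p, miR-377-3p and miR-434-3p had changes of 0.05, 0.11 and -0.043; with scaling on the spike-ins 6 fell. All 13 tested members of the Sfmbt2 cluster were below 0, with a median of -0.38, but only miR-467b-5p passed, and it was at background in mutant arrays and turned positive with normexp correction and with the total signal. With no scaling 10 of the 13 fell (median -0.71), and with scaling on the spike-ins 8. The camera adjusted p was 0.414 and 0.151 for these lists. Without wild-type replicate 2, 1 member of the Dlk1-Dio3 cluster fell, and 0 without any other array; without wild-type replicate 3, 2 members of the Sfmbt2 cluster fell and that list passed, and 0 fell without any other array. Of 135 tested high-numbered entries, which were taken as a sign of RNA quality, 5 rose and 16 fell (camera adjusted p = 0.819). These counts depended on the scaling: 0 rose and 64 fell with no scaling, 0 and 41 with the percentile over all probes, 2 and 48 with the spike-ins, 4 and 27 with the total signal, and 7 and 2 with normexp correction. The rises were 1, 1, 2, 2 and 3 without wild-type replicates 1 and 2 and mutant replicates 1, 2 and 3, and the falls 7, 5, 3 and 7 without wild-type replicates 1 and 2 and mutant replicates 1 and 3. They included miR-7036a-5p and miR-7216-5p, which fell 1.91-fold and 1.86-fold. MiR-6961-5p was at least 2.06-fold lower, miR-7222-3p at least 1.42-fold, and miR-3075-5p and miR-7007-5p at least 1.34-fold, all at background in mutant arrays; with normexp correction none of these 6 passed, and the changes were -0.18 for miR-7036a-5p, -0.23 for miR-7216-5p, -0.16 for miR-6961-5p, -0.015 for miR-7222-3p, 0.00044 for miR-3075-5p and -0.0081 for miR-7007-5p. Outside the lists, miR-681 was at least 1.60-fold lower (change -0.085 and not past the threshold with normexp correction), and miR-101c and miR-101a-3p, which are similar in sequence, fell 1.82-fold and 1.78-fold.

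**Figure D3:**
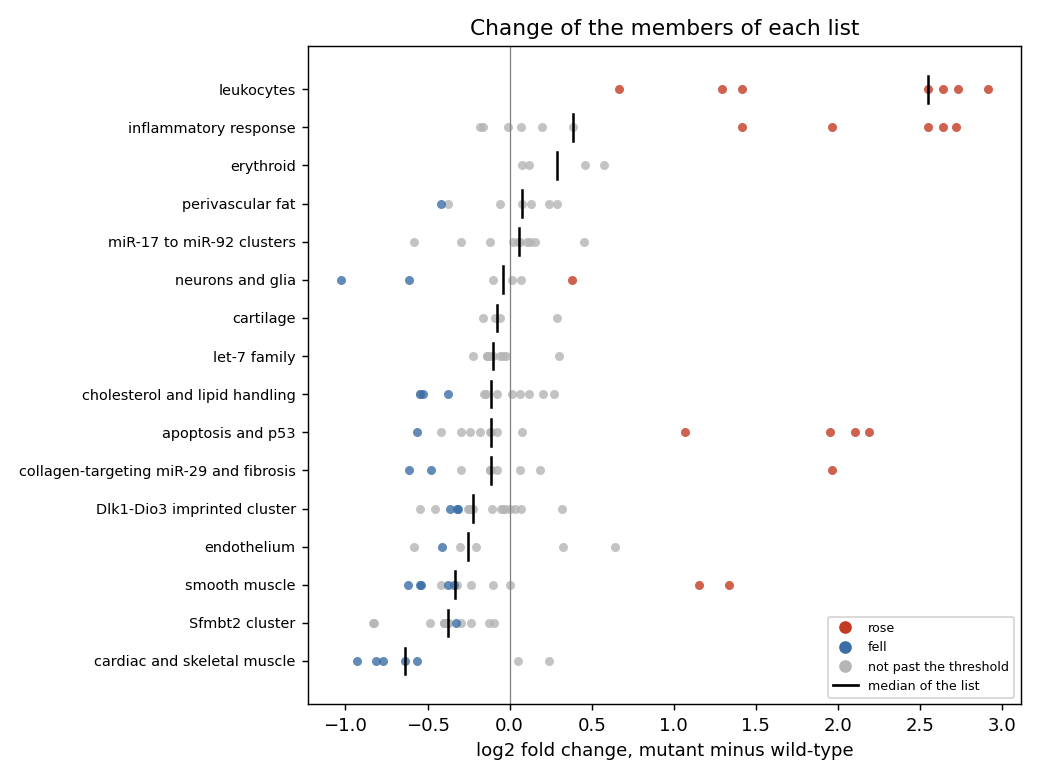
Change (log2, mutant minus wild-type) of each tested member of 16 lists; red points rose, blue points fell, grey points did not pass, and black bars are list medians. The leukocyte list stands highest with a median of 2.55, and the cardiac and skeletal muscle list lowest with -0.63; the 135 high-numbered entries are not drawn.

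A further 14 miRNAs were detected by the software on all 3 arrays of one genotype and on none of the other, 5 in mutant and 9 in wild-type arrays. Of these, only miR-142a-5p passed. In mutant arrays the others were miR-21a-3p, miR-3081-5p, miR-342-5p and miR-532-3p, and in wild-type arrays let-7e-3p, miR-3110-3p, miR-3620-5p, miR-466g, miR-5118, miR-7014-5p, miR-703, miR-7075-5p and miR-714. No fold is given for these 13, since at most 1 array of a genotype had a probe well above background.

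The precision is limited by 3 mice per genotype, and leaving out single arrays gave between 42 and 67 calls in place of 94: 42, 53 and 52 without mutant replicates 1, 2 and 3, and 60 without wild-type replicate 2. Row 1 of the slide held the wild-type arrays and mutant replicate 3, and row 2 the other mutant arrays: with the row as a block 68 miRNAs passed (31 rose, 37 fell), and within row 1 alone, 3 arrays against 1, 17 passed (13 rose, 4 fell), with the leukocyte and inflammatory lists past the threshold in both at the preset correlation. With an estimated correlation, fitted without a block, 0 lists passed. Both the block and row 1 alone compare mutant replicate 3 with the wild-type arrays. Across 392 miRNAs that array had a Pearson r of 0.939 to 0.962 with wild-type arrays, against 0.969 to 0.979 for the other mutant arrays.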

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

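Scaling on the labelling spike-ins, the slide column as a covariate and the outlier spots kept were chosen after seeing the data. The lists of leukocytes and inflammatory response stayed past the threshold in the same direction under every alternative run with the preset correlation, and with an estimated correlation 0 lists passed. The 7 tested leukocyte miRNAs stayed above 0 under every alternative whose fit included them, but 6 passed with no scaling and without mutant replicate 1, 5 with the row block and with the total signal (lowest change 0.0080), 4 within row 1 and 3 with no filter. The 5 smooth muscle falls became 2 with the authors' table, 3 with the row block and with detection on all 6 arrays, and 0 within row 1 and with no filter. Of the 43 named miRNAs past the threshold, 16 kept both sign and call under every alternative whose fit included them but no filter and row 1 alone (miR-142a-5p had no fit with detection on all 6 arrays). They include miR-342-3p, miR-142a-3p, miR-146a-5p, miR-146b-5p, miR-21a-5p, miR-34a-5p, miR-221-3p, miR-222-3p, miR-1a-3p, miR-133a-3p, miR-133b-3p, miR-143-3p, miR-101a-3p, miR-101c, miR-30c-5p and miR-142a-5p.

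Counts moved more than that. With no scaling 157 miRNAs passed (16 rose, 141 fell; 70 shared with the 94) and 33 had an unadjusted p under 0.05 and at least a 2-fold change; with the spike-ins 147 passed (125 fell; 83 shared). With the percentile over all probes 20 rose. Normexp gave 59 calls (27 falls; 44 shared) and 10 at 2-fold, and 17 of the 43 named calls did not pass, 5 of them with the sign turned; the total signal gave 49 at 2-fold. Without a detection filter 8 of 1881 passed (8 rose, 0 fell) and 8 lists. The row block gave 37 falls and 39 at 2-fold, and row 1 alone 17 calls (13 rose, 4 fell) and 36 at 2-fold. The cause of these moves was not tested, apart from the 1881 miRNAs tested and the single mutant array in row 1, which follow from the settings. Leaving out single arrays gave 42 (mutant replicate 1) to 67 calls, 21 to 30 rises, 21 to 43 falls and 2 to 4 lists. The median of all miRNAs moved by -0.16, -0.29, -0.17, 0.20 and -0.20 with all probes, no scaling, spike-ins, normexp and total signal, so small changes are relative to that. No difference in miRNAs detected per array moved beyond 1 SD.

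Of all 94 calls, 15 had the opposite sign with normexp, 8 with the total signal and 1 with no scaling, whether or not they then passed. Among named calls signs turned in 8 cases. With normexp, miR-3075-5p was at 0.00044, miR-133a-5p at 0.025, miR-377-3p at 0.11, miR-376c-3p at 0.049 and miR-467b-5p at 0.13; with the total signal, miR-34b-5p was at -0.79, miR-7a-5p at -0.036 and miR-467b-5p at 3.39. Of these 7 miRNAs, 4 were at background in mutant arrays, where the signal over background limits what can be measured; the cause was not tested.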

Other observations

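The explanations and hypotheses below, and the groups in the next paragraph, were all chosen after the values their tests use had been seen, in full or in part, and the criteria for slide row, slide column and GC content were tightened after their results.

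All 5 tested 5p members of the miR-30 family fell, by 0.78 for miR-30b-5p (SE 0.10, adjusted p = 0.00767), 0.77 for miR-30d-5p, 0.57 for miR-30e-5p, 0.55 for miR-30c-5p and 0.32 for miR-30a-5p. Their sequences are similar, so the probes are not independent. With single arrays left out, miR-30e-5p passed only without mutant replicate 1. Its limma adjusted p was 0.065, 0.076 and 0.063 without wild-type replicates 1, 2 and 3. On the X chromosome, 3 of 6 tested miRNAs of a cluster within Clcn5 rose: miR-532-5p by 0.94 (SE 0.18, adjusted p = 0.0225), miR-362-3p by 0.62 and miR-188-5p by 0.48. MiR-188-3p, miR-500-3p and miR-532-3p did not pass. MiR-15b-5p was the only one of 6 tested members of the miR-15 and miR-16 family to pass, and none of the 4 tested miR-181 members passed.

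A hypothesis was that miRNAs from one genomic cluster, or from one hairpin, change together. Over 163 pairs of tested miRNAs that share no precursor and lie within 10000 bases, the mean product of centred changes was 0.0834, at the 99.3rd percentile of 10000 shuffles. In 13 pairs both members passed, and all 13 moved the same way, among them miR-143-3p with miR-145a-5p, miR-1a-3p with miR-133a-3p and miR-221-3p with miR-222-3p. Some loci enter more than once, such as miR-1a-3p with both arms of miR-133a, so the pairs are not independent. The largest products came from miR-34b-5p with miR-34c-5p (changes 2.10 and 1.95) and miR-221-3p with miR-222-3p (1.15 and 1.33). The mean product was not computed without them. MiR-133b-3p and its neighbour miR-206-3p had changes of -0.77 and 0.05. Across 38 precursors with both arms tested, the Spearman rho of the changes of the arms was 0.68, and in the 5 with both arms past the threshold they moved the same way. Both are in line with changes in the amount of precursor, although miRNAs are not independent replicates and similar probe sequences may add to it.

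The leukocyte miRNAs rose while muscle miRNAs fell. The tables argue against scaling as the source, since over 6 other scalings or corrections the leukocyte median was at least 1.17 and the muscle median at most -0.52. With the same ratio of white to red cells in both genotypes, more retained blood would raise red-cell miRNAs as much as leukocyte ones. That ratio was not measured. The upper 95% bound of the change of the mean of 3 erythroid miRNAs was 1.21, below the leukocyte median of 2.55. Without wild-type replicate 3 the change of that mean was 0.70 (upper bound 1.22), against 0.39 with all arrays, and the erythroid list passed. The highest upper bound without 1 array was 1.56, against a lowest leukocyte median of 2.42. MiR-511-3p, miR-142a-5p and miR-223-3p, at 0.67, 1.29 and 1.42, lay below that highest bound, so blood stays open for these members. As the cause of the leukocyte rise, a lower share of smooth muscle would raise other cell types about as much, and the highest median among endothelium, fat, neurons and cartilage was 0.077; the endothelial miR-126a-3p and miR-126a-5p had changes of 0.64 and 0.33. A lower share stays open for the muscle falls. The slide row stays open for the rise and for the falls, since row 2 held mutant arrays alone. Of the mutant arrays, mutant replicate 3 had the lowest correlations with the wild-type arrays (Pearson r 0.939 to 0.962). With the row as a block, which rests on mutant replicate 3 as the only mutant array in row 1, the leukocyte median was 2.62, with 5 of 7 members past the threshold, and the muscle median -0.71, with 4 of 7. MiR-223-3p, miR-511-3p and miR-30e-5p no longer passed, at 1.52 (SE 0.32) against 1.42 (SE 0.20), 0.63 (SE 0.16) against 0.67 (SE 0.10) and -0.71 (SE 0.16) against -0.57 (SE 0.12), since the errors grew. Within row 1 alone, where mutant replicate 3 is the only mutant array, the changes are those of the block, with other errors. For miR-155-5p and miR-142a-5p, whose wild-type values were all at the floor, these errors do not measure spread. More leukocytes in the mutant aorta, lymphoid tissue taken along, or a change within aortic cells may each account for the rise and stay open.

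Within both genotypes some miRNAs have a positive slope on the column of the array on the slide, with miR-344c-5p and miR-762 among the steepest and highest on mutant replicate 3, although miR-344c-5p was higher on wild-type replicate 2 than on wild-type replicate 3. Across 392 miRNAs the column slope in wild-type arrays had a Pearson r of 0.56 with that in mutant arrays, and 2 of the 36 orders of arrays within genotypes gave as much, the next reaching 0.54. Position along the slide and the mouse itself cannot be told apart, since within a genotype each column held at most 1 mouse. GC content of the probe also stays open: over all miRNAs its Spearman rho with the slope was -0.046, but the 10 steepest had a median GC of 64.3% against 53.3%. The rho of GC content was -0.17 with the wild-type slopes and 0.062 with the mutant slopes, which differ in sign. With the column as a covariate 101 miRNAs passed, 79 of them among the 94, and no biological explanation was tested.

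All 13 tested Sfmbt2-cluster members had a change below 0, although only miR-467b-5p passed and the list did not (camera adjusted p = 0.151). A shared repeat in the probes is a candidate explanation: 12 of the 13 probes hold one, and the 8 such probes outside the list had a median change of -0.37, with 3 of them, miR-1187, miR-3082-5p and miR-574-5p, at -0.99, -1.01 and -0.84, let-7k and miR-377-3p, both at background in mutant arrays, at -0.37 and -0.36, and let-7b-5p, miR-206-3p and miR-574-3p between -0.019 and 0.051. Background correction is another, since the list's median was 0.023 with normexp; with no scaling 10 of the 13 fell. A change in transcription of the cluster with genotype stays open.

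With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. For the 94 calls 1 split, the real one, gave as many, and the highest other split gave 0. For the 18 miRNAs at 2-fold 1 split gave as many, and the highest other gave 3. For the 2 lists past the threshold 9 splits gave as many, and the highest other gave 6. Every other split mixed both genotypes on each side in unequal numbers. Part of the genotype difference therefore stayed in its comparison and in its spread. The counts of the other splits do not give a rate of false calls.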
